A study of Homo sapiens with 6 samples.

How the data were processed

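RNA sequencing libraries came from 3 human hepatocellular carcinoma cell lines, MHCC97L, MHCC97H and HCCLM3. Each line was sequenced once without ligand and once after 4 h with 2.5 ng/mL TGF-β1, giving 6 libraries in 2 conditions. Total RNA was extracted with Trizol and made into libraries by standard Illumina steps, per the labels' protocols. The labels name neither the kit nor whether it marks strand, and they do not say whether the 2 libraries of a line came from separate cultures.

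The authors deposited expected counts per gene, 1 file per library, with Ensembl gene IDs. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff 1.3.0 and the genome build hg38, without roles. The tool that made the counts is not given in the sources used here. The values are called expected counts from the values themselves: 63.6% to 64.6% of the values in a library were whole numbers, zeros included, and the others had decimals, as arises when a read that matches several genes is divided among them. The files gave 22091 gene IDs, of which 19574 matched a symbol in the gene name table of the reference set or, failing that, in the GENCODE 29 annotation of GRCh38. Coordinates and overlaps came from the same annotation. The other 2517 IDs held 2.01% of the counts and stayed in the library sizes and tests under their IDs. A further 44 IDs whose symbol belonged to 2 or more IDs were also shown by ID. Expected counts were rounded to whole numbers before any count model, which changed a library's total by at most 134 counts. Counts were whole in all 6 libraries for 12560 genes before rounding, and 3476 genes were at 0 in every library.

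Totals were 22854982, 20407269 and 18485041 in the control libraries of MHCC97L, MHCC97H and HCCLM3, and 23085194, 23242862 and 21257080 in their TGF-β1 libraries. A count of 0 allows up to 3 counts, which is 0.129 to 0.162 CPM (counts scaled by library size) in a single library. Counting intervals are 95% exact conditional binomial intervals of the ratio of 2 counts. Reads carried no molecular identifiers, so intervals and floors cover counting error only.

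Tests were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Genes were kept by filterByExpr on the treatment groups, which asks for expression in at least 3 libraries. That left 14176 genes, 846 of them with no symbol. Libraries were scaled by TMM, with factors from 0.972 to 1.029. TGF-β1 against control was tested with edgeR's quasi-likelihood F test (robust, bias-adjusted deviances) with cell line and treatment as terms, which leaves 2 residual degrees of freedom, and with Benjamini-Hochberg adjustment at 0.05. The same fit gave the 3 comparisons between cell lines. The comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

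The pairing comes from the labels, which give each line with and without ligand. It was checked by correlating the deviations of the 2 libraries of a line from their condition means across genes, which gave 0.587 in MHCC97L, 0.456 in MHCC97H and 0.728 in HCCLM3.

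Within a line there is 1 library per condition, so fold changes are log2 differences of CPM with a prior count of 2 and have no test. Genes with a CPM of 5 or more in either library were counted at 2-fold. Where a count was 0, the fold is a bound against 3 counts in that library. Where 2 lines were compared and a line had 0 counts, the bound was taken against 3 counts over its 2 libraries together. Responses of the lines were compared by Pearson's r and Spearman's rho across genes and by the number of genes at 1.5-fold or more in the same direction in all 3 lines, set beside the number that independent lists would share.

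Gene lists were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01) with Benjamini-Hochberg adjustment over the 23 lists with at least 5 measured genes. In all, 24 lists were written: SMAD targets, ID and BMP targets, YAP/TAZ targets, TGF-β and Hippo pathway components, mesenchymal genes, epithelial genes, extracellular matrix genes, ligands that activate stellate cells, hepatocyte genes, liver progenitor and oncofetal genes, cell cycle genes, cytostatic response genes, immediate early genes, interferon-stimulated genes, unfolded protein and amino acid stress genes, hypoxia genes, cholesterol synthesis genes, NF-kB and inflammation genes, p53 targets, ribosomal proteins, mitochondrially encoded genes, and markers of stellate cells and fibroblasts, of endothelium and of leukocytes. Every symbol was found except 1 of the 16 progenitor and oncofetal genes. Some genes stand on several lists. Within each line, a list's median fold change was ranked among medians of 10000 random lists matched on mean expression in 20 bins.

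For TGF-β1 the text names CCN1 in any case, then the 12 genes that rose and the 12 that fell most among genes past the threshold that moved the same way in all 3 lines and had a mean CPM of 5 or more. Up to 4 members with the smallest p are named for each list. Within a line the 5 genes that rose and the 5 that fell most with a CPM of 10 or more in either library are named, and between lines the 5 higher and 5 lower genes with the largest change among those past the threshold with a CPM of 10 or more in a library. Other list members, and genes whose response differed between lines, were chosen after their values were seen. XIST and Y-linked genes were left out.

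Alternatives covered scaling by edgeR's RLE, by upper quartiles and by library totals, other count filters, the DESeq2 Wald test, limma-voom, non-robust and legacy quasi-likelihood, a fit without the line or the treatment term, other prior counts and CPM minimums, an estimated correlation in camera, the rotation test fry, and leaving out each line. Several were added after the data were seen: genes with a symbol only, genes with whole counts only, no mitochondrially encoded genes, all libraries thinned to 18484954 counts, 1 library left out for the line comparisons, DESeq2 and limma-voom without the line term, upper-quartile and library-total scaling for the lists, and the test of whether a line's response differs from the mean of the other 2.

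The fits were tested on simulated counts drawn from the real means, library sizes and dispersions, with a known fold put into a random set of genes. For the line comparison the lines were first made alike. For TGF-β1 against control over 13996 genes, 66.7% of genes changed 1.5-fold were recovered, 80.3% at 2-fold and 96.9% at 4-fold, and 23 of 182 calls were unchanged genes. For HCCLM3 against MHCC97L over 14016 genes the shares were 51.5%, 80.3% and 93.8%, with 22 unchanged genes among 170 calls. For the response of HCCLM3 against the other lines over 14001 genes they were 23.1%, 53.1% and 76.6%, and 52 of 150 calls were unchanged genes, so that test calls more false genes than its threshold states. That test takes its spread only from the difference between the other 2 lines. A simulated change in 1 list among 22 gave an adjusted p of 1.21e-27 by camera and put 0 other lists past the threshold, and with no change 0 lists passed. Genes were drawn independently of each other, so this does not show how camera behaves where genes of a list move together. With no response simulated over 14001 genes, r between lines lay between -0.012 and 0.006.

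Genes whose counts were not whole may share reads with other genes, which was not tested, and among the 14176 tested genes there were 7603 of these. In addition, 677 tested IDs had counts identical to another ID in every library, including ID3, TRIM27 and TDO2, whose partners have no symbol. With the strand of the counting not given, a gene and an overlapping partner on the opposite strand cannot be separated here either.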

Results

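RNA was measured by sequencing in 3 human hepatocellular carcinoma cell lines, each grown without ligand or given TGF-β1 at 2.5 ng/mL over 4 h. MHCC97L and MHCC97H were derived from one parental tumour line and chosen for low and high metastatic potential, and HCCLM3 was derived from lung metastases of MHCC97H. There are 6 libraries, 3 per condition and 1 per line and condition, with total expected counts of 22854982, 20407269 and 18485041 in the controls of MHCC97L, MHCC97H and HCCLM3 and 23085194, 23242862 and 21257080 after TGF-β1. With 1 library per line and condition, a p value for the treatment measures the spread of the response between lines, not between cultures of a line. Changes are TGF-β1 minus control on the log2 scale with their standard error (SE), n = 3 lines, adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and levels are in CPM (counts scaled by library size) ± SD over the 3 lines.

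The first comparison asks which genes respond to TGF-β1 in all 3 lines. CCN1, also called CYR61, which encodes a secreted matrix-associated protein and is named in the series title, rose by 1.88 (SE 0.215), from 7.65 ± 1.8 to 29.1 ± 11.4 CPM. PMEPA1, which encodes a SMAD-induced inhibitor of the pathway, rose by 3.30 (SE 0.109), from 12.2 ± 9.27 to 121 ± 88.1 CPM. The secreted growth factor PDGFB rose by 2.76 (SE 0.324) and the transcription factor JUNB by 2.33 (SE 0.099), from 90.2 ± 26.6 to 444 ± 79.1 CPM. KITLG, which encodes the KIT ligand, fell by 1.17 (SE 0.098), from 17.9 ± 2.19 to 7.93 ± 0.64 CPM, and the hepatocyte transcription factor gene CEBPA fell by 1.05 (SE 0.11), from 87.8 ± 21.5 to 44.0 ± 17.5 CPM.

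Of 14176 genes tested, 2047 passed an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), of which 1104 rose and 943 fell. The share that rose, 53.9%, depends on the scaling: it was 44.2% with upper quartiles and 37.1% with library totals. A change of 2-fold or more was seen in 233 of them, 197 that rose and 36 that fell, and 2041 moved the same way in all 3 lines. Genes with a symbol made up 1977 of the 2047. The count rests on which lines are in the fit: it was 611 without MHCC97L, 981 without MHCC97H and 3971 without HCCLM3. With a line left out, the spread comes only from the difference in response between the lines that remain. A call lost in such a fit does not alone show that the gene's response depends on the line left out. On simulated data 23 of 182 calls of this comparison were unchanged genes, a larger share than the threshold of 0.05.

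CCN1 (ENSG00000142871.16, hg38 chromosome 1, 85580761 to 85583962) rose 3.67-fold with an adjusted p of 0.00685 (edgeR quasi-likelihood, Benjamini-Hochberg), by 1.22 in MHCC97L, 2.24 in MHCC97H and 2.13 in HCCLM3. It had whole counts in all libraries and no overlapping gene. Without HCCLM3 its adjusted p was 0.0784 by the same method, in a range of 2.82e-16 to 0.154 over its alternatives.

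The genes named next passed the threshold, had a symbol and a mean of 5 CPM or more, and were chosen to move the same way in all 3 lines. Among those that rose most, RND1 went from 9.18 ± 0.89 to 63.4 ± 2.11 CPM, a change of 6.89-fold with an adjusted p of 3.1e-06 (edgeR quasi-likelihood, Benjamini-Hochberg). The secreted lipase inhibitor gene ANGPTL4 rose 6.86-fold, the adhesion receptor gene ADGRG1 7.66-fold and the keratin gene KRT17 6.77-fold. SEMA7A, a membrane-anchored semaphorin gene, rose 5.64-fold, the cytokine gene IL11 4.82-fold, FOSB 4.52-fold, the glucose transporter gene SLC2A3 4.38-fold and SAMD11 4.31-fold. SLC2A3 rose by 2.52 in MHCC97L, 2.11 in MHCC97H and 0.90 in HCCLM3. The adjusted p of PDGFB, 0.0345 (edgeR quasi-likelihood, Benjamini-Hochberg), was the largest among these genes. Leaving out 1 line ended some calls: without MHCC97L or MHCC97H the adjusted p of PDGFB was 0.27 or 0.0721 (range over its alternatives 1.18e-12 to 0.27, edgeR and the other tools), without HCCLM3 that of ADGRG1 was 0.161 (2.82e-50 to 0.218) and that of SEMA7A 0.139, its highest, and without MHCC97H that of SLC2A3 was 0.116 (1.92e-08 to 0.465) and that of SAMD11 0.0916 (4.66e-10 to 0.246). Counts were not whole, as can arise when reads are divided between genes, for ADGRG1, ANGPTL4, KRT17, IL11, FOSB, SLC2A3 and SAMD11, and PMEPA1, ANGPTL4, JUNB, FOSB and SAMD11 overlap NKILA, RAB11B-AS1, HOOK2, ERCC1 and NOC2L on the opposite strand, so these values are uncertain.

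Among genes with a symbol and a mean of 5 CPM or more, chosen in the same way, those that fell most changed less than those that rose most. CAVIN2, which encodes a caveolar coat protein, fell by 1.38 (SE 0.122), from 26.1 ± 14.6 to 10.5 ± 7.14 CPM, and the co-receptor gene TGFBR3 fell by 1.36 (SE 0.144). SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 1.33 on the log2 scale, ATOH8 by 1.24 and the stem cell factor SOX2 by 1.22. The WNT receptor ligase gene RNF43 fell by 1.17 on the log2 scale, ANKRD33B by 1.11, the receptor kinase gene MERTK by 1.08, BIRC3 by 1.07 and FLRT3 by 1.02. BIRC3, which encodes an apoptosis inhibitor, went from 56.0 ± 11.3 to 26.6 ± 4.61 CPM. TGFBR3, RNF43 and BIRC3 did not have whole counts, SOX2 lies within SOX2-OT, RNF43 overlaps SUPT4H1 and FLRT3 overlaps MACROD2, so these values are uncertain.

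**Figure D1:**
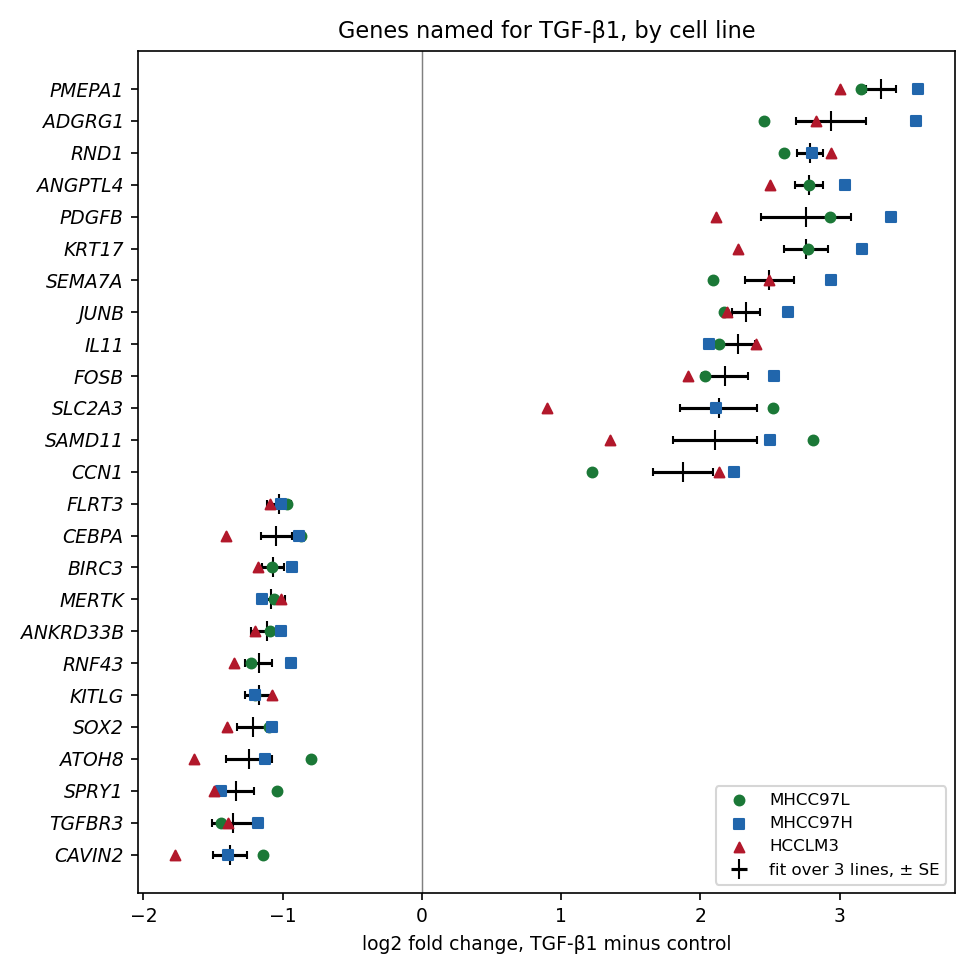
Change after TGF-β1 (log2, treated minus control) of CCN1 and the genes with a symbol and a mean of 5 CPM or more that rose or fell most, with a point per cell line and the fitted mean ± SE. PMEPA1 has the largest rise of the genes drawn, 3.30. Genes other than CCN1 were drawn only if they passed the threshold and moved the same way in all 3 lines. Their lines lie on the same side of 0 by that choice.

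Of 31 measured targets of SMAD transcription factors 24 rose and 0 fell past the threshold by edgeR, with 1 that fell at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom, and 24 rose and 1 fell when adjusted over the list alone. The median change was 0.84. Camera called the list higher (adjusted p 5e-14), a call lost at an adjusted p = 0.577 with an estimated correlation. That correlation was estimated from only 2 residual degrees of freedom, so it is poorly known. A call lost under it, here or for other lists, does not show that the list stayed unchanged. PMEPA1, JUNB, IL11 and the cell cycle inhibitor gene CDKN2B (1.55, SE 0.095) had the smallest p. The collagen gene COL7A1 rose by 1.79, FSTL3 by 1.63, PTHLH by 1.62 and TGFBI by 1.42. The inhibitory SMAD gene SMAD7 rose by 1.19 (SE 0.081). ARRDC4, TSC22D1 and INHBA had changes of -0.27, -0.23 and -0.16, none past the threshold, though TSC22D1 passed when adjusted over the list alone (0.00979).

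Of 20 measured ligand genes that activate hepatic stellate cells, the question raised by the series title, 13 rose, also 13 when adjusted over the list alone, with a median of 0.59. Besides PDGFB, IL11 and CCN1 these included FGF2 (1.29, SE 0.098), PDGFA (1.19, SE 0.088), CCN2 (1.17, SE 0.16) and VEGFA (0.63). FGF2 overlaps NUDT6, ADAM19 overlaps CYFIP2 and CDKN2B, named among the SMAD targets, overlaps CDKN2B-AS1, each on the opposite strand, so these values are uncertain. Among 24 extracellular matrix genes 14 rose and 3 fell, and 15 and 3 when adjusted over the list alone. COL1A1 rose by 3.93 (SE 0.243) from a low level, ADAM19 by 1.33, ITGA2 by 0.96 and LOX by 0.85, while ADAMTS1 fell by 0.89 on the log2 scale, LAMA3 by 0.58 and FN1 by 0.42. Of 19 mesenchymal genes 9 rose and 1 fell, and 13 and 1 when adjusted over the list alone, with rises in the integrin gene ITGA5 (1.18, SE 0.078), SNAI2 (1.32, SE 0.094), SNAI1 (0.69, SE 0.108), CNN1 (1.97) and VIM (0.53). By DESeq2 6 rose and 1 fell. The list's summed share of counts fell after TGF-β1 in each line. It went from 1.508% to 1.244% in MHCC97L, from 1.767% to 1.347% in MHCC97H and from 1.523% to 1.258% in HCCLM3. The matrix list's share fell too, from 1.539% to 1.297%, 1.763% to 1.397% and 1.597% to 1.328% in the same order. Without MHCC97L the adjusted p of FN1 was 0.159 (edgeR quasi-likelihood; range over its alternatives 3.42e-08 to 0.266).

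Immediate early genes included 12 of 26 that rose and 2 that fell, and 14 and 3 when adjusted over the list alone. By DESeq2 9 rose and 2 fell. EGR2 rose by 1.91, JUN by 1.14 and KLF2 by 0.99, and DUSP5 and MYC fell by 0.29 and 0.26 on the log2 scale. Of 19 hypoxia genes 6 rose, and 7 when adjusted over the list alone, among them the glucose transporter gene SLC2A1 (0.95), SLC2A3, VEGFA and ANKRD37 (0.73). By DESeq2 4 hypoxia genes rose, and 10 ribosomal protein genes. Of 46 ribosomal protein genes 7 rose, and 8 when adjusted over the list alone, with a median of 0.15, and RPS14 (0.40), RPS20 (0.38), RPL13 (0.35) and RPS19 (0.31) had the smallest p. Without MHCC97L none of these 4 ribosomal genes, nor MYC or ANKRD37, passed by edgeR's quasi-likelihood test, with an adjusted p of 0.245 for RPS14 (range over its alternatives 3.28e-05 to 0.286), 0.278 for RPS20, 0.263 for RPL13, 0.313 for RPS19, 0.475 for MYC (0.00202 to 0.475) and 0.195 for ANKRD37 (0.00537 to 0.547). The same 6 genes lost their calls without MHCC97H, with an adjusted p of 0.0924 for RPS14, 0.0974 for RPS20, 0.133 for RPL13, 0.113 for RPS19, 0.137 for MYC and 0.105 for ANKRD37. Calls were also lost with library totals for RPS19 (0.0564) and RPL13 (0.0612), by DESeq2 (0.118) and with thinned libraries (0.0547) for ANKRD37, and with no count filter (0.0657) and non-robust quasi-likelihood (0.0502) for MYC. SLC2A1 and ANKRD37 overlap SLC2A1-AS1 and UFSP2 on the opposite strand.

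By camera with a preset correlation, these 7 of 23 lists were higher after TGF-β1, and the adjusted p was 5e-14 for SMAD targets, 5.37e-06 for ligands, 8.38e-06 for mesenchymal genes, 1.04e-05 for ribosomal proteins, 0.000114 for matrix, 0.000114 for immediate early genes and 0.0162 for hypoxia. With an estimated correlation 0 lists passed and 1 had an unadjusted p under 0.05: SMAD targets had an adjusted p = 0.577 with an estimated correlation, ligands 0.577, mesenchymal genes 0.577, matrix 0.701, immediate early genes 0.732, ribosomal proteins 0.732 and hypoxia 0.734. The rotation test fry called 2 lists, SMAD targets and mesenchymal genes, each with an adjusted p of 0.0469. Camera with the preset correlation also called up to 6 lists when the libraries were split into 3 and 3 in other ways. Without MHCC97L the hypoxia list had an adjusted p of 0.09 by camera, in a range of 0.00266 to 0.734 over its alternatives. The median of that list was 0.26 in MHCC97L, 0.08 in MHCC97H and -0.01 in HCCLM3, at percentiles 99.97, 78.65 and 37.31 among random lists matched on expression.

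**Figure D2:**
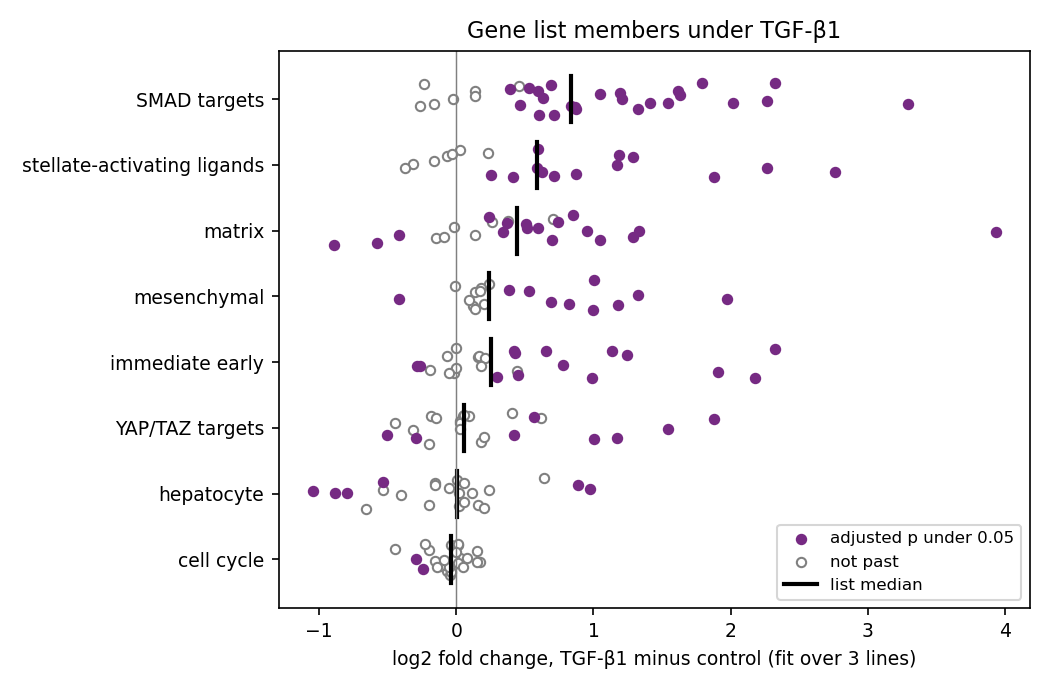
Change after TGF-β1 (log2, fitted over 3 lines) of each measured member of 8 gene lists, with a bar at each list's median. The SMAD targets have the highest median, 0.84.

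YAP/TAZ targets, the other pathway in the series title, went both ways. Of 23 genes 6 rose and 2 fell, and 8 and 3 when adjusted over the list alone. CCN1, CCN2, the coagulation factor receptor gene F3 (1.55, SE 0.095), NUAK2 (1.01), GADD45A (0.56) and CCDC80 (0.42) rose, IGFBP3 and MYOF fell by 0.51 and 0.30 on the log2 scale, and ANKRD1, at 0.62, did not pass. The list's median was 0.06, with an adjusted p of 0.224 by camera, and 0.737 with an estimated correlation. Without MHCC97L camera gave 0.0266, in a range of 0.0266 to 0.737, and GADD45A had an adjusted p of 0.0625 by edgeR (range 0.000311 to 0.705). Among pathway components TGFBR3, TGFBR2 (-0.59), ACVR1B (-0.36), TEAD1 (-0.33) and YAP1 (-0.30) fell and ACVR1 (0.48), TGFBR1 (0.44) and VGLL4 (0.26) rose. That is 3 that rose and 5 that fell of 23, the same numbers when adjusted over the list alone, with an adjusted p of 0.522 by camera. Without MHCC97L the adjusted p of TGFBR1 was 0.111 (range 0.00232 to 0.295) and that of ACVR1 0.0703 (9.77e-05 to 0.203) by edgeR. Of 6 ID and BMP targets, ATOH8, ID2 (-0.68) and ID3 (-0.51) fell, and 1 rose and 3 fell when adjusted over the list alone. Camera gave an adjusted p of 0.224. ID3 has the same counts as an ID with no symbol and ID2 overlaps ID2-AS1, so both values are uncertain.

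Epithelial genes went both ways, with 4 of 18 that rose and 2 that fell, and 4 and 3 when adjusted over the list alone. The tight junction gene CLDN4 rose by 1.12, JUP by 0.77, KRT8 by 0.29 and KRT18 by 0.26, and ESRP2 and PKP2 fell by 0.61 and 0.59 on the log2 scale. CDH1, which encodes E-cadherin, had a change of -0.16 and did not pass. The median was -0.08 and the mean 0.03, and camera, which took the direction as down, gave an adjusted p of 0.975. Without MHCC97L the adjusted p of ESRP2, which overlaps NFATC3, was 0.166 (range 0.00496 to 0.355, with 0.0752 by DESeq2), that of PKP2 0.0648 (0.000116 to 0.646) and that of SERPINA1 0.0694 (3.38e-06 to 0.879) by edgeR. Hepatocyte genes also went both ways. HNF4A rose by 0.97 (SE 0.071) and SERPINA1 by 0.89, and those that fell included CEBPA, NR1H4 (-0.88) and APOB (-0.80). In all 2 rose and 4 fell of 23, and 2 and 5 when adjusted over the list alone, with a median of 0.004, a mean of -0.09 and an adjusted p of 0.583 by camera. HNF4A overlaps an antisense gene and did not have whole counts.

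Within each line, the question is how large the response is in lines of different metastatic potential. There is no replicate check within a line, so only values are given, with 95% exact binomial intervals for counting error. PMEPA1 went from 21.0 to 187 CPM in MHCC97L, from 12.96 to 154 in MHCC97H and from 2.5 to 20.7 in HCCLM3. PDGFB changed by 2.93 in MHCC97L (2.77 to 3.11) and 3.37 in MHCC97H (3.15 to 3.62), and RND1 by 2.94 in HCCLM3 (2.72 to 3.21). KITLG changed by -1.20 in MHCC97L (-1.47 to -0.95) and ATOH8 by -1.64 in HCCLM3 (-2.00 to -1.34). These 5 genes had whole counts.

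Of genes with a CPM of 5 or more in either library, 184 of 11063 changed 2-fold or more in MHCC97L (141 higher after TGF-β1, 43 lower), 271 of 11116 in MHCC97H (199 and 72) and 195 of 11060 in HCCLM3 (144 and 51). KRT16 changed by 2.82 in MHCC97L, ADGRG1 by 3.55, KRT17 by 3.16 and ANGPTL4 by 3.04 in MHCC97H, and NRSN1 by 2.94 in HCCLM3, while RNF43 changed by -1.23 in MHCC97L. SMAD targets had medians of 0.62, 0.93 and 0.96 in MHCC97L, MHCC97H and HCCLM3, each at percentile 100 among 10000 random lists matched on expression.

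Some of the largest changes within a line were in genes whose counts were not whole. These may share reads with near-identical copies or read-through partners, which was not tested, so their values and bounds are uncertain. In MHCC97L, DUSP14 went from 6 to 284 counts and RGPD6 from 7 to 287, and MDC1 went from 365 to 2 (a change of -6.46, interval -10.53 to -5.62). LSM14A changed by -3.36 in that line and TRIM27 went from 297 to 73 counts. In MHCC97H, SHANK3 went from 227 to 0 counts, at least 83.9-fold lower against 3 counts in the library at 0, SULT1A4 from 346 to 3 (-6.22, interval -9.28 to -5.44), LSM14A changed by -4.20, RPL36A-HNRNPH2 by -2.25 and RGPD6 by -1.79. In HCCLM3, LHX1 went from 0 to 311 counts, at least 94.5-fold higher on the same basis, MDC1 from 6 to 312, and SULT1A4, RBM14-RBM4, DDX24 and ISY1-RAB43 changed by -2.10, -2.05, -2.03 and -1.75.

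The responses of the lines were then set against each other. Genes at 1.5-fold or more in the same direction in all 3 lines, such as CCN1, which went from 1.22 to 2.24, and KITLG, numbered 278 higher and 115 lower after TGF-β1, where independent lists would share 3.6 and 2.24. Across 14176 genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.426 (Spearman's rho 0.615) between MHCC97L and MHCC97H, 0.284 (0.401) between MHCC97L and HCCLM3 and 0.254 (0.334) between MHCC97H and HCCLM3. The same sign was seen for 75.2%, 64.3% and 61.2% of genes. Among genes with whole counts r was 0.728, 0.567 and 0.538.

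The last comparison asks how the lines differ from each other, with treatment as a term and 2 libraries per line. These are 1 control and 1 TGF-β1 library, not replicates of the line. A p value between lines therefore takes its spread from how the lines differ in their response to TGF-β1, not from cultures of a line. Some genes of hepatocyte function were lower in HCCLM3, the line from lung metastases. SERPINA1, which encodes alpha-1-antitrypsin, was lower by -6.50 (SE 0.184) against MHCC97L, with 0.91 against 84.2 CPM, and by -5.42 (SE 0.188) against MHCC97H. The fibrinogen gene FGB was lower by -7.10 (SE 0.237) and the albumin gene ALB by -4.08 (SE 0.205) against MHCC97H. The cancer-testis antigen gene SSX1 was higher in HCCLM3, with 139 CPM against 1.08 in MHCC97L, and by 5.18 (SE 0.14) against MHCC97H.

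By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4229 of 14176 genes differed between HCCLM3 and MHCC97L (2133 higher in HCCLM3, 2096 lower), 3849 between HCCLM3 and MHCC97H (1883 and 1966) and 348 between MHCC97H and MHCC97L (194 higher in MHCC97H, 154 lower). At 2-fold or more there were 1238, 1109 and 144. On simulated data 22 of 170 calls between HCCLM3 and MHCC97L were unchanged genes, a larger share than the threshold of 0.05. The count filter asks for expression in at least 3 libraries, so genes expressed in 1 line only, which has 2, were not tested. COL3A1, at 14.7 and 11.4 CPM in HCCLM3 and at or under 0.392 CPM in the other lines, was among them. With no count filter 4163, 3742 and 333 genes differed. The count of 348 rests on single libraries: it was 96 without the MHCC97L control, 136 without MHCC97L after TGF-β1, 1284 without the HCCLM3 control and 1486 without HCCLM3 after TGF-β1. The 4229 fell to 2091 and 2065 without the control and the TGF-β1 library of MHCC97L.

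Against MHCC97L, HCCLM3 was higher in the basement membrane collagen gene COL4A5 (6.28), BCAT1 (5.58), CPED1 (5.47) and FGF13 (5.27) and lower in MUC5B (-6.85), ADAMTS10 (-5.98), TNS1 (-5.52) and COBL, which had 1 count in HCCLM3 and 897 in MHCC97L (ratio interval -14.91 to -7.12). Against MHCC97H it was higher in ZBED2 (5.40), SPANXD (5.21), SSX1 and BCAT1 (4.98) and lower in MUC5B (-6.94), the alcohol dehydrogenase gene ADH1C (-6.78), KRT4 (-6.61) and COBL (1 count against 666, ratio interval -14.52 to -6.73). MHCC97H was higher than MHCC97L in ITM2A (5.22, SE 0.215), the cadherin gene CDH6 (3.64), IL7R (3.26), SLC38A5 (2.05) and ADGRG6, with 403 counts against 91, and lower in CREB5 (-2.80), the connexin gene GJA1 (-2.66), SPANXA1 (-1.65) and SLC2A3, with 187 counts against 896. SPANXD lost its call against MHCC97H with limma-voom (adjusted p 0.0614) and legacy quasi-likelihood (0.057). With no treatment term the calls of TNS1 (adjusted p 0.0782, edgeR quasi-likelihood), CDH6 (0.185), ADGRG6 (0.242), SLC38A5 (0.085), CREB5 (0.0546), GJA1 (0.336) and SPANXA1 (0.0621) were lost. That fit counts the change after TGF-β1 as spread, so a call can be lost there though the line difference holds in both conditions. SLC2A3 lost its call with legacy quasi-likelihood (adjusted p 0.0656), without the MHCC97H control (0.211, edgeR quasi-likelihood), without MHCC97L after TGF-β1 (0.082), without MHCC97H after TGF-β1 (0.371) and, at its highest over all alternatives, with no treatment term (0.798). LHX1 had 0 counts in MHCC97H, which makes it at least 18.9-fold lower than in MHCC97L, with 58 counts, and at least 111-fold lower than in HCCLM3, against 3 counts over the 2 libraries at 0. The difference from MHCC97L passed by edgeR's quasi-likelihood test but not by DESeq2 (adjusted p 0.859), limma-voom (0.663), legacy quasi-likelihood (0.745), with no filter (0.769), without the TGF-β1 library of MHCC97H (0.381) or, at its highest, with no treatment term (0.938). That from HCCLM3 was also lost by DESeq2 (0.219), limma-voom (0.287), legacy quasi-likelihood (0.475), with no filter (0.383) and with no treatment term (0.253). All 311 counts of HCCLM3 came from its TGF-β1 library, and without that library the adjusted p against MHCC97H was 1.0 by edgeR, the highest over its alternatives. Counts were not whole for SERPINA1, SSX1, BCAT1, FGF13, MUC5B, SPANXD, ADH1C, CDH6, IL7R, SLC38A5, LHX1, SLC2A3 and SPANXA1, and families such as SSX and SPANX hold near-identical copies, so these values are uncertain.

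Of 23 measured hepatocyte genes 18 were lower in HCCLM3 than in each of the other lines, and 19 when adjusted over the list alone, with medians of -2.37 against MHCC97L and -2.12 against MHCC97H. AMBP was lower by -2.73 and -2.41, and the transferrin gene TF and the retinol carrier gene RBP4 by -2.60 and -2.59 against MHCC97L. Camera gave adjusted p values of 6.88e-11 and 2.15e-11, which became an adjusted p = 0.639 and an adjusted p = 0.376 with an estimated correlation. Of 19 mesenchymal genes 10 were higher and 1 lower in HCCLM3 than in MHCC97L, and 13 higher and 1 lower than in MHCC97H, and 12 and 1 and 15 and 1 when adjusted over the list alone. SPARC was higher by 4.02 and 2.09, ZEB2 by 1.24 and 0.94 and the N-cadherin gene CDH2 by 0.69 and 0.74, while S100A4 was lower (-0.28 and -0.31). Camera gave an adjusted p of 0.00526 and 0.00016, and an adjusted p = 0.639 and 0.376 with an estimated correlation. Epithelial genes differed both ways: of 18, 4 were higher and 7 lower than in MHCC97L, and 4 and 8 than in MHCC97H, and 5 and 7 and 4 and 10 when adjusted over the list alone, with an adjusted p of 0.252 and 0.0972 by camera. The tight junction genes CLDN1 (-3.09 and -2.49) and TJP3 (-3.45 and -4.14) were lower, and CLDN4 (1.04 and 0.97) and PKP2 (0.74 and 1.03) higher.

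**Figure D3:**
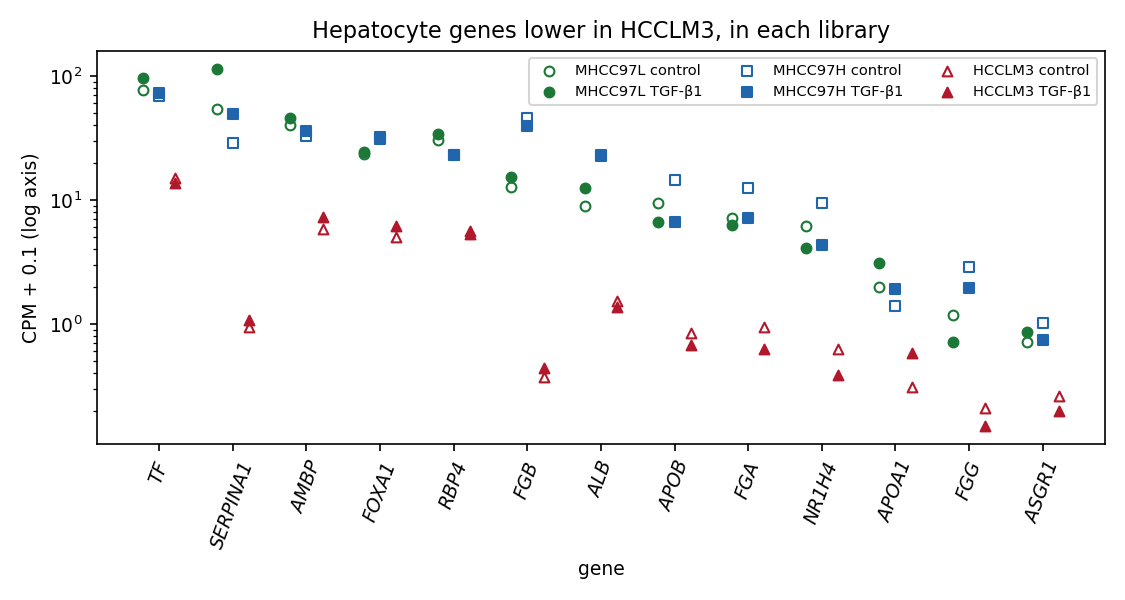
Level of the hepatocyte genes that were lower in HCCLM3 than in both other lines by a log2 fold change of more than 1 (CPM plus 0.1, log axis) in each of the 6 libraries, by line and condition. SERPINA1 is at 0.85 and 0.969 CPM in HCCLM3 and at 54.2 and 114 CPM in MHCC97L, without and with TGF-β1.

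SMAD targets were higher in HCCLM3 in 16 and lower in 4 of 31 against MHCC97L, and 17 and 4 when adjusted over the list alone, and against MHCC97H in 17 and 2, and 19 and 2 when adjusted over the list alone. PTHLH was higher by 2.72 and 2.26 and IL11 by 1.53 and 2.18, while PMEPA1 was lower by -3.18 and -2.72. Cholesterol synthesis genes were lower in HCCLM3 than in MHCC97H in 11 of 20, and 12 when adjusted over the list alone, with FDFT1 at -0.73 and DHCR7 at -0.69. Between MHCC97H and MHCC97L 3 of these genes were higher in MHCC97H, and 10 when adjusted over the list alone, with LSS at 0.83 and DHCR7 at 0.51. NF-kB and inflammation genes were lower in MHCC97H than in MHCC97L in 3 of 17, and 7 when adjusted over the list alone, with CXCL8 at -1.04, IL32 at -0.64 and BIRC3 at -0.51. Calls between these 2 lines, of cholesterol genes too, are fragile. A fit with no treatment term counts the change after TGF-β1 as spread. Of 41 named genes and list members past the threshold between these lines, 39 lost their call in that fit. Most also lost it when either library of MHCC97L was left out.

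Besides hepatocyte and mesenchymal genes, camera called SMAD targets (adjusted p 0.034 against MHCC97L and 0.000169 against MHCC97H), cytostatic response genes (0.0192 and 0.0123), immediate early genes (0.0416 and 0.00151) and hypoxia genes (0.0192 and 0.000777) higher in HCCLM3. Each of these 4 lists had an adjusted p = 0.639 with an estimated correlation against MHCC97L, and against MHCC97H an adjusted p = 0.559, 0.558, 0.56 and 0.559 in the same order. Ligands that activate stellate cells were higher than in MHCC97H (0.00394), with CXCL8 at 2.15 and FGF2 at 1.06, and cholesterol genes lower (0.000386), while interferon-stimulated genes (0.0491) and ribosomal proteins (0.034) were lower than in MHCC97L. With an estimated correlation the adjusted p = 0.559 for ligands, 0.376 for cholesterol genes and 0.639 for both other lists. In MHCC97H against MHCC97L cholesterol genes (8.16e-06) and ID and BMP targets (0.0102) were higher, and ribosomal proteins (1.88e-05), NF-kB genes (1.88e-05), interferon-stimulated genes (0.000126), ligands (0.00351), YAP/TAZ targets (0.00354), SMAD targets (0.0102) and unfolded protein and amino acid stress genes (0.0183) lower. With an estimated correlation the adjusted p = 0.553 for SMAD targets and 0.53 for each of the others.

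By camera 8 of 23 lists differed between HCCLM3 and MHCC97L, 8 between HCCLM3 and MHCC97H and 9 between MHCC97H and MHCC97L. With an estimated correlation 0 lists passed in each comparison, with an unadjusted p under 0.05 for 1, 3 and 1, and fry called 10, 13 and 1. The estimate rests on only 2 residual degrees of freedom here too, so these lost calls cannot decide whether the lists differed.

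The 13 mitochondrially encoded genes held a share of counts that moved apart between lines after TGF-β1. It went from 6.15% to 5.03% in MHCC97L, from 6.17% to 3.67% in MHCC97H and from 4.76% to 6.55% in HCCLM3. All 13 genes were lower after TGF-β1 in MHCC97L and MHCC97H and all 13 higher in HCCLM3, with medians of -0.31, -0.83 and 0.59. Over the 3 lines 0 of these genes passed by edgeR, DESeq2 or limma-voom, and 0 had an unadjusted p under 0.05 by any of them. The list median was -0.15, with an adjusted p of 0.428 by camera, which became 0.000248 without HCCLM3, in a range of 0.000248 to 0.821.

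**Figure D4:**
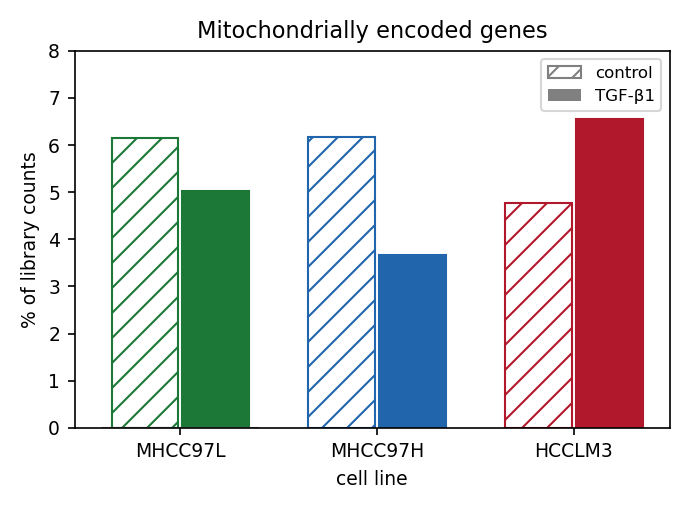
Share of each library's counts in mitochondrially encoded genes (percent), by cell line and condition, 1 library per bar. The share is lower after TGF-β1 in MHCC97L and MHCC97H and higher in HCCLM3, at 6.55%.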

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

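The test of whether a line's response differed from the mean of the other 2 was added after the data were seen, as were the tests on genes with whole counts and of single libraries. It sets the single pair of libraries of a line against the other 2 lines, so its spread comes only from the difference in response between those 2 lines, with 1 residual degree of freedom. On simulated data 52 of 150 calls were unchanged genes. Its calls therefore do not show that a line responds differently, and fitted differences are given as values.

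For the growth factor gene PDGFB the fitted difference of HCCLM3 from the other lines was -1.02 on the log2 scale, with changes of 2.93, 3.37 and 2.11 in MHCC97L, MHCC97H and HCCLM3. For the hepatocyte factor gene CEBPA it was -0.53, with changes of -0.87, -0.88 and -1.41. In MHCC97H the difference was 0.96 for the adhesion receptor gene ADGRG1 and 0.90 for the keratin gene KRT7.

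Other differences past the threshold of that test in HCCLM3 were those of LSM14A (4.22), DDX24 (-2.53), RBM14-RBM4 (-1.62), TRIM27 (1.54), SAMD11 (-1.34), RPS14 (-0.43) and LHX1, which had 311 counts in 1 library of the line and 0 in the other, so its fitted difference of 10.39 depends on the prior count. In MHCC97H SHANK3 had a fitted difference of -11.35 from a library at 0. In MHCC97L they were those of DUSP14 (5.68), NRSN1 (-2.03) and LHX1 (-9.31, fitted). Of these genes only PDGFB and CEBPA had whole counts. Further differences of genes with whole counts in HCCLM3, chosen after their values were seen, were those of IGFBP1 (-1.30), CA9 (-1.07), OXTR (1.35), TGFBI (-0.58) and ID1 (-0.60), and in MHCC97H FSTL3 (0.78) and JUN (0.67).

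List tests of the response of 1 line have the same limit. Camera with a preset correlation placed SMAD targets (adjusted p 0.0183), YAP/TAZ targets (0.00798), stellate-activating ligands (0.0283) and immediate early genes (0.0183) lower in MHCC97L and hepatocyte genes higher (0.00779), SMAD targets (0.0124) and immediate early genes (0.00189) higher in MHCC97H and mitochondrially encoded genes lower (1.44e-06), and mitochondrially encoded genes higher in HCCLM3 (5.42e-09). SMAD targets had an adjusted p of 0.965 in HCCLM3, the line with their highest median, 0.96. Each of the lists past the threshold had an adjusted p = 0.824 with an estimated correlation in MHCC97L, 0.917 in MHCC97H and 0.977 in HCCLM3.

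That test put 225 genes past its threshold in HCCLM3, 54 in MHCC97H and 26 in MHCC97L by edgeR. MHCC97L and MHCC97H responded most alike (r 0.426, against 0.284 and 0.254 with HCCLM3), so the spread is taken from the closest pair where HCCLM3 is set apart, and the larger count may come from the design. With all libraries thinned to one total the counts were 202, 12 and 26, and among genes with whole counts 192, 23 and 0, with 83 at an unadjusted p under 0.05 for the last. Of those 192 and 23 genes 58 and 2 were also past the threshold among all genes. The count in HCCLM3 was 142 with RLE scaling. Because the test cannot separate the lines, depth, shared reads, variation between single libraries and a difference in biology, which was not tested, cannot be told apart as causes of the larger count.

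Mitochondrially encoded genes moved down in MHCC97H and up in HCCLM3, with medians of -0.83 and 0.59. The values argue against normalization as the cause, since over 5 scalings the smaller median kept a size of at least 0.519. They also argue against GC content or length, since 342 matched nuclear genes had a median 0.098 of the list's in HCCLM3 and moved slightly the other way in MHCC97H. Variation between single libraries cannot be told apart from a response of the lines, because each line has 1 library per condition and the larger adjusted p = 0.977 with an estimated correlation.

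Genes that moved 1.5-fold or more in opposite directions in 2 lines numbered 309. Their rate was 3.31 times as high (95% interval 2.52 to 4.35) among genes whose counts were not whole, 245 of 7603 against 64 of 6573 (Fisher's exact p = 3.42e-21, two-sided). Interval and p take genes as independent, but IDs with identical counts were counted separately and mitochondrially encoded genes moved together. Both therefore overstate the certainty. At a mean CPM of 10 or more the rate was 0.0395 of that below (0.0259 to 0.0604). Reads shared between copies and counting noise may thus each contribute, and among genes with a mean CPM of 10 or more the ratio for counts that were not whole was 4.54 (1.55 to 13.3). That ratio rests on 19 genes whose counts were not whole and 4 with whole counts. Both groups hold mitochondrially encoded genes, such as MT-CO3 in the first and MT-ND1, MT-ND3 and MT-ND6 in the second. No biological explanation was tested.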

How the results depend on the processing

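Tests on genes with symbols or whole counts only, without mitochondrial genes, with thinned libraries, without single libraries of the line comparisons and with DESeq2 and limma-voom without the block were chosen after the data were seen, as was the test of responses differing between lines, whose spread comes from only 2 lines. All 82 named genes that passed for TGF-β1 kept their direction under every alternative that tested them. That was nearly fixed beforehand, since 2041 of the 2047 genes past the threshold had moved the same way in all 3 lines. Of the named genes 82 still passed with limma-voom, legacy quasi-likelihood and upper quartiles, 74 with DESeq2, 55 without MHCC97L, 64 without MHCC97H and 78 without HCCLM3. The cause of a change was not tested unless fewer genes or samples explain it.

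Without the line as a block, so without the pairing, 10 genes passed for TGF-β1 by edgeR (10 rose, 0 fell, with 783 that fell at an unadjusted p under 0.05), 501 by DESeq2 (316 rose, 185 fell) and 11 by limma-voom (11 rose, 0 fell, with 802 that fell at an unadjusted p under 0.05). Of the 82 named genes 3 then passed by edgeR, RND1, ANGPTL4 and COL1A1, and CCN1 had an adjusted p of 0.154 (range 2.82e-16 to 0.154). Leaving out a line gave 611 to 3971 genes (423 to 2148 that rose, 188 to 1823 that fell): 611 without MHCC97L, 981 without MHCC97H and 3971 without HCCLM3, with fewer libraries. With the block DESeq2 gave 536 that fell against 943, and the cause was not tested. PDGFB lost its call without MHCC97L and without MHCC97H, ADGRG1 and SEMA7A without HCCLM3, and SLC2A3 and SAMD11 without MHCC97H, with the values beside those genes in the comparison.

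For lists, 0 passed with an estimated correlation (1 unadjusted) and 2 by fry, against 7, and leaving out a line gave 7 to 8. The correlation was estimated from 2 residual degrees of freedom, so its lost calls cannot decide whether the lists moved. Hypoxia lost its call without MHCC97L (0.09) and the mitochondrial list passed without HCCLM3 (0.000248, median -0.56), with a median of 0.15 without MHCC97H. For the lines an estimated correlation gave 0 in each (unadjusted 1, 1 and 3) and fry 1 for MHCC97H against MHCC97L and 13 for HCCLM3 against MHCC97H, against 9 and 8.

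Without the treatment term 2 genes differed between MHCC97H and MHCC97L, 1780 between HCCLM3 and MHCC97L and 1440 between HCCLM3 and MHCC97H. That fit counts the change after TGF-β1 as spread, so its lower counts do not bear on the line differences alone. Genes with whole counts gave 2533 and 2364 for the last pair of comparisons, with fewer genes tested. Leaving out 1 library gave 96 to 1486, 2065 to 4643 and 2780 to 4417. The LHX1 difference between HCCLM3 and MHCC97H was 0 in the control libraries alone.

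Genes at 2-fold within MHCC97L, MHCC97H and HCCLM3 numbered 395, 540 and 418 at a CPM minimum of 1, 77, 131 and 90 at 20, and 98, 149 and 108 with whole counts. Between MHCC97L and MHCC97H r was 0.342 with a prior count of 0.5, 0.491 with 5, 0.703 at a mean CPM of 10 or more, 0.529 with symbols and 0.728 with whole counts. Between MHCC97L and HCCLM3 the last 3 gave 0.528, 0.381 and 0.567, and between MHCC97H and HCCLM3 0.492, 0.376 and 0.538, with 0.179 at a prior count of 0.5. Genes that rose in all 3 lines numbered 144 at a mean CPM of 10 or more, 107 at 2-fold, 643 at the lowest fold tried and 158 with whole counts, and those that fell 48, 14, 514 and 72.

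Genes past the threshold of the test of responses numbered 0 in MHCC97L with whole counts (83 unadjusted, edgeR), 30, 23, 30 and 12 in MHCC97H with symbols, whole counts, no mitochondrial genes and thinned libraries, and 142 in HCCLM3 with RLE. Depth limits genes at low counts, where 3 counts are 0.129 to 0.162 CPM.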

Other observations

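The chemokine genes CXCL2, CCL20 and CXCL5 fell by 1.17, 0.66 and 0.54 on the log2 scale after TGF-β1, as did CXCL3 at a mean of 1.42 CPM, while IL32 rose by 0.43 and NFKB1 by 0.29. With BIRC3 that makes 5 of 17 NF-kB and inflammation genes that fell and 2 that rose, and 5 and 4 when adjusted over the list alone, with an adjusted p of 0.431 by camera. Among 18 p53 targets CDKN1A rose by 1.21, PHLDA3 by 0.87, TP53I3 by 0.86, BTG2 by 0.84 and PLK3 by 0.60, and GDF15 fell by 0.54 on the log2 scale, 5 and 1 in all and also 5 and 1 when adjusted over the list alone (camera adjusted p 0.164). Without MHCC97L the adjusted p of CXCL3 was 0.0825 and that of IL32 0.0825 by edgeR, in ranges of 0.00525 to 0.305 and 0.000635 to 0.92, and that of CXCL3 was 0.0756 without MHCC97H and 0.109 by DESeq2. CDKN1A overlaps DINOL on the opposite strand.

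Of 9 cytostatic response genes CDKN2B and CDKN1A rose and CDC25A (-0.43) and MYC (-0.26) fell, and 5 rose and 3 fell when adjusted over the list alone (camera adjusted p 0.413). Of 28 cell cycle genes MKI67 (-0.29) and MCM6 (-0.24) fell by edgeR, with 4 by limma-voom, and 0 when adjusted over the list alone, with 6 at an unadjusted p under 0.05 and a camera adjusted p of 0.271. MKI67 had an adjusted p of 0.0497 by edgeR's quasi-likelihood test, but its call was lost with RLE scaling (0.0526), no count filter (0.0719), the CPM filter (0.0506), non-robust quasi-likelihood (0.0621) and thinned libraries (0.0526), and without MHCC97L it was 0.366, in a range of 0.00039 to 0.366. Of 20 stress genes of the unfolded protein and amino acid response DDIT4 (0.77), SESN2 (0.49), HERPUD1 (0.36) and SDF2L1 (0.33) rose and STC2 (-0.70) fell, and 4 and 2 when adjusted over the list alone (camera adjusted p 0.367). Interferon-stimulated genes had OASL at 0.52 and OAS3 and IFIT3 at -0.25 and -0.51 past the threshold of 23 measured, and 2 that rose and 3 that fell when adjusted over the list alone (camera adjusted p 0.599). Of 20 cholesterol synthesis genes 1 rose and 1 fell by edgeR, and 0 when adjusted over the list alone, with 3 and 2 at an unadjusted p under 0.05, 0 and 1 by DESeq2 and 1 and 1 by limma-voom (camera adjusted p 0.583). Of 10 measured liver progenitor and oncofetal genes 0 passed by edgeR or limma-voom and 1 rose by DESeq2, also 0 when adjusted over the list alone, with 2 at an unadjusted p under 0.05. KRT7, which overlaps KRT86, was at 0.90 and KRT19 at 0.22 (camera adjusted p 0.583). Without MHCC97L several of these calls were lost by edgeR, with an adjusted p of 0.356 for MCM6 (range 0.0148 to 0.489), 0.106 for CDC25A (0.00328 to 0.444), 0.475 for MYC, 0.0606 for SESN2 (0.00206 to 0.246), 0.223 for HERPUD1 (0.0175 to 0.263), 0.0955 for OASL (0.000934 to 0.793), 0.363 for OAS3 (0.0124 to 0.363), and 0.127 for IFIT3, which overlaps LIPA (0.0263 to 0.646). Without MHCC97H the calls of MKI67 (0.246), MCM6 (0.0789), CDC25A (0.0534), MYC (0.137), HERPUD1 (0.0762), OAS3 (0.0821) and IFIT3 (0.165) were lost too, as were those of CDC25A (0.0574), HERPUD1 (0.105) and IFIT3 (0.203) by DESeq2 and that of MYC with no count filter (0.0657) and non-robust quasi-likelihood (0.0502).

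COL1A1, a fibroblast collagen gene, went from 0.306, 0.49 and 0.433 CPM in the controls of MHCC97L, MHCC97H and HCCLM3 to 7.02, 5.68 and 5.41 after TGF-β1, while COL1A2 stayed at or under 0.39 CPM, PDGFRB at or under 0.26 and ACTA2 at or under 0.131. COL3A1 was at 14.7 and 11.4 CPM in HCCLM3. Of 5 measured stellate and fibroblast markers COL1A1 rose, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p 0.164). Of the 10 endothelial markers 4 were measured, too few for a list test, and PECAM1 fell by 0.39 on the log2 scale, with an adjusted p of 0.101 by edgeR without MHCC97L and 0.169 without MHCC97H, and 0.0971 by DESeq2 (range 0.0174 to 0.898). Of 5 measured leukocyte markers 0 passed by edgeR, DESeq2 or limma-voom, 0 of them at an unadjusted p under 0.05. Their median was -0.06 and their mean 0.05, with the direction up and an adjusted p of 0.644 by camera. PTPRC was at or under 0.131 CPM, and CD68 lay between 109 and 239 CPM. At 1 CPM or more in a library were 5 of the 13 stellate, 5 of the 10 endothelial and 4 of the 14 leukocyte markers.

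The 6 libraries make only 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2047 genes and the highest other 2, and 1 split gave as many. In the other splits the change after TGF-β1 is counted as spread, so few genes can pass. The gap in genes was thus largely fixed by the design and says nothing about chance. The real split gave 7 lists and the highest other 6, and again 1 split gave as many. Among the 4 splits that part all 3 lines the highest other gave 1 gene and 6 lists, and the other 6 splits part 1 line.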
